A study of Homo sapiens with 6 samples.

How the data were processed

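GABPA ChIP-seq was analysed in A-375 cells under 3 conditions, namely parental cells, cells with a ROSA26 knockout, and cells with a knockout of exon 2 of the GABP B1 subunit followed by a TERT knock-in. Each condition has 1 ChIP sample and 1 input sample in the labels, 6 samples in all. The 3 ChIP samples each have 1 peak list, and the 3 lists were the only measurements used here. The input samples were not analysed here on their own. Per the labels' protocols, knockout lines were grown from single sorted cells and chromatin was recovered with 1 GABPA antibody. The TERT knock-in is stated in the series' design text, and the sample titles name a TERT rescue.

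Reads were aligned with Bowtie2, handled with SAMtools and turned into peaks with MACS2 on the hg38 build, per the submitters' processing notes. Tool versions, duplicate handling, thresholds and the use of the input as a control are not given in the sources used here. The lists were called per ChIP sample, since each sample has its own list. Peak numbers within each list run without a gap up to the number of rows (3024, 3857 and 1660), so no peak was left out after numbering. The fold enrichment of each peak is the authors' own value, the ratio of the pileup at the summit to the local background as the deposited lists give it. The deposited lists also give the −log10 of the p-value and of the q-value of each summit, and a score that equals 10 times the −log10 q-value with the decimals dropped. Fold, −log10 p and −log10 q were used only to rank, filter or describe peaks within their own list, except for −log10 p scaled to another library's background, and no direction was read from folds of different lists. All coordinates are hg38, written 1-based.

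The lists hold no read totals. The pileup at each summit was therefore solved from fold and −log10 p with the formula of MACS2, in which fold is (pileup + 1)/(background + 1), the p-value is a Poisson tail and the pileup is a whole number of reads times 1 scale factor per library. A solution within 0.01 in −log10 p was found for all peaks of each list. The background shared by the largest number of peaks, in the library's own reads, was 15.4 in the parental, 14.2 in the ROSA26 and 9.86 in the B1 knockout library. This value grows with read depth and fragment length together, and the B1 knockout library reached 64.0% of the parental and 69.3% of the ROSA26 value. After the scale factor of each library (0.860 parental, 1 ROSA26, 0.924 knockout) the backgrounds were 13.3, 14.2 and 9.11. Scaling of −log10 p to another library's background used these scaled values, in which ROSA26 and not the parental library stood highest. The median peak summit had 132, 122 and 82 reads in the same order. The solver recovered the reads of all peaks in 3 simulated lists with known answers.

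Peaks were called shared when they overlapped by at least 1 bp. Control-shared peaks are parental peaks overlapped by a ROSA26 peak. Merged regions join overlapping peaks of the 3 lists. Shares are given with exact Clopper-Pearson 95% intervals over peaks or genes, which cover counting error only, since neighbouring peaks and reads without molecular identifiers are not independent. With 1 library per condition no test between conditions was made and no p-value is given.

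Gene positions came from a RefSeq gene table of GRCh38.p14, whose coordinates are those of hg38. It gives 19970 protein-coding genes on chromosomes 1 to 22 and X as spans, and strand, transcripts and sequence were not used here. A gene was therefore called occupied when a summit lay within 1 kb of either end of its span, so that start and end were not distinguished and internal starts were missed. The planned promoter, CpG and divergent-promoter measures were replaced by this measure, by matching on span length and by neighbouring gene ends. The planned counts of ETS motifs at summits were not run because no genome sequence was used here. A peak counted for every gene with an end within reach, and peaks between neighbouring genes are named with both genes where they matter. Peaks off these chromosomes (5 parental, 17 ROSA26 and 8 knockout) count as not near a gene end. As background, the same distance was measured at 20000 random positions.

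Before the data were examined, 27 gene lists, the groups, the comparisons, the alternatives and the rule for named genes were fixed. The lists hold 926 distinct genes found in the table. For occupancy, each list was set against 10000 random lists of protein-coding genes matched on 5 bins of span length and on having another gene's end within 1 kb. For the share kept in the knockout, it was set against 10000 random lists of genes with a peak in both controls, matched on 10 bins of parental fold. The percentile counts a tie as 0.5 of a list and describes these libraries only. In simulated lists drawn from the 3062 genes with a peak in both controls, 4.7% of unaffected lists of 14 genes lay below the 2.5th or above the 97.5th percentile. Lists of 14 genes whose chance of being kept was set to 0.5 of that of other genes fell below the 2.5th percentile in 81.7% of simulations, and lists of 30 genes in 99.3%. The simulations drew kept or not kept for each gene on its own. Genes of 1 list that share a peak, such as HARS1 and HARS2, were not modelled, so real lists may spread more widely. A limit of at least 5 genes for counting a list was set after the values were seen.

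The rule for named genes took the GABP subunits and TERT, the 5 genes at the strongest parental peaks near a gene end, and up to 2 kept and 2 not kept genes per list with the highest parental fold. It also took the 5 strongest control-shared peaks without a knockout peak and the 5 strongest knockout peaks with no control peak. The genes that the rule would name in the MAPK list are not reported here. Genes named outside this rule are marked as chosen after their values were seen. Alternatives covered stricter −log10 q limits of 5 and 10, other definitions of overlap, lists of equal length, other distances to gene ends, other rankings and scaling to the knockout background. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.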

Results

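GABP is a transcription factor built from GABPA, an ETS family protein that contacts DNA, and a B subunit encoded by GABPB1 or GABPB2 that carries the activation domain and joins GABP units together. The genomic positions of GABPA were measured by ChIP-seq in A-375, an established human melanoma cell line. Parental cells and cells with a knockout at ROSA26, a locus commonly used as a neutral target, were the 2 controls. The third condition combined a knockout of exon 2 of the B1 subunit with a knock-in of TERT, the catalytic subunit of telomerase. The comparison asks where GABPA peaks are found in cells with this knockout and knock-in. There was 1 ChIP library per condition, so the differences below have no replicate check. The B1 knockout, the knock-in and the particular clone belong to the same library, and no sample separates them. The lists hold 3024 parental, 3857 ROSA26 and 1660 B1 knockout peaks, with median widths of 585, 636 and 513 bp. The background pileup recovered from the peak values was 15.4, 14.2 and 9.86 reads, a value that grows with read depth and fragment length together.

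The genes of GABP itself differed in their peaks. GABPA (chromosome 21, 25734972 to 25772460) had a peak in all 3 lists, with its parental summit at 25735062, 90 bp inside the gene's span. The fold enrichment, which is the authors' own value for each peak here and throughout, was 13.2 in the parental, 14.3 in the ROSA26 and 12.5 in the B1 knockout list. The same peak lay 591 bp inside the end of ATP5PF, a subunit of ATP synthase. GABPB1 (chromosome 15, 50275389 to 50355198), the targeted gene, had a peak 281 bp from the end of its span in the parental list (fold 9.39) and 301 bp from it in the ROSA26 list (fold 10.3), and none in the knockout list. The peak lists do not show the edit of the gene itself, and the position of the guides was not used here, so this difference is no check of the knockout. Scaled down to the background of the knockout library, the GABPB1 peaks of the controls kept a −log10 p of 64.7 and 90.1. GABPB2 (chromosome 1, 151070761 to 151125542), which encodes the other B subunit, had weak peaks in both controls (fold 2.74 and 3.78) and none in the knockout list. The scaled values were 8.08 in the parental and 17.6 in the ROSA26 library. In the knockout list the lowest −log10 p was 4.74 and the 10th percentile 13.6. After scaling, 2965 of 2969 control-shared peaks pass the lowest value, so passing it does not show that a peak should have been listed. No peak was listed within 1 kb of, or inside, TERT (chromosome 5, 1253167 to 1295068) in any of the 3 libraries. A position without a listed peak is below the peak caller's limit and is not shown to be unbound.

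Fewer regions carried a GABPA peak in the B1 knockout library, and nearly all of those that did were shared with the controls. Of 3936 merged regions, 1628 were listed in all 3 libraries, 1335 in both controls only, 886 in ROSA26 only, 55 in parental only, 8 in ROSA26 and the knockout, and 24 in the knockout only. Among the 2969 control-shared peaks, 1628 had a knockout peak, which is 54.8% (95% interval 53.0 to 56.6), and 1341 had none. In the reverse direction, 98.1% of the 1660 knockout peaks (97.3 to 98.7) had a peak in both controls. The controls differed from each other as well. Of the parental peaks 98.2% (97.6 to 98.6) had a ROSA26 peak, whereas 76.8% of the ROSA26 peaks (75.5 to 78.1) had a parental peak. Of all parental peaks 53.8% (52.0 to 55.6), and of all ROSA26 peaks 42.4% (40.9 to 44.0), had a knockout peak.

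**Figure D1:**
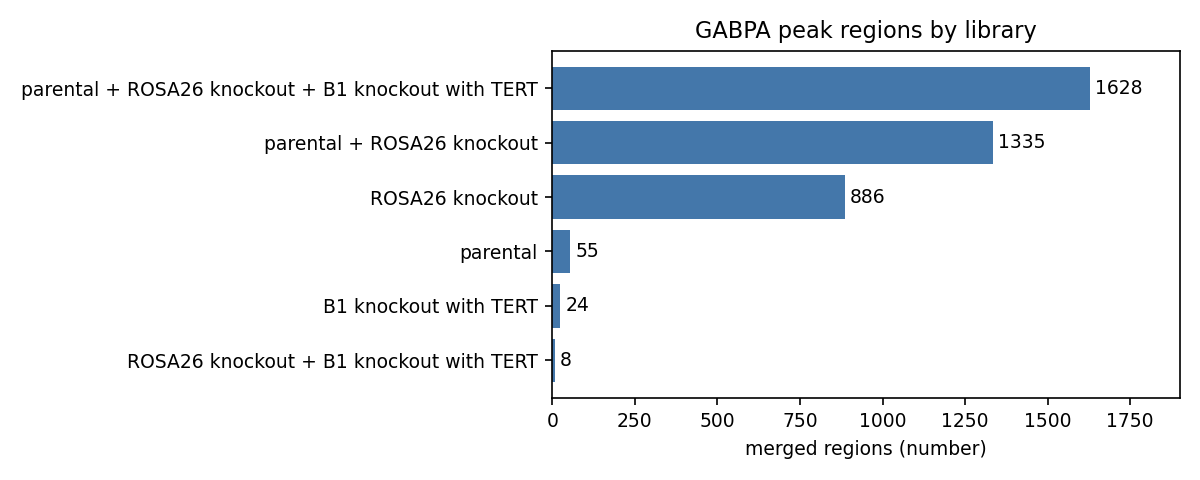
Number of merged GABPA peak regions (x axis) for each combination of libraries that list a peak there (y axis), 1 library per condition. The regions listed in all 3 libraries (1628) and in both controls only (1335) are the largest classes, and 24 regions are listed in the B1 knockout only.

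List length sets part of these shares, so lists of equal length were compared too. With the top 1660 peaks of each list by −log10 p, 94.1% of the parental peaks (92.9 to 95.2) had a ROSA26 peak and 86.5% (84.8 to 88.1) had a knockout peak. Of the ROSA26 peaks, 85.9% (84.1 to 87.5) had a knockout peak. The intervals of the knockout comparisons lie below that of the control pair. At equal length the share of control-shared peaks with a knockout peak was 88.2%, in place of 54.8% over whole lists.

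The strongest GABPA sites of the parental cells were still listed in the knockout. The 5 genes at the strongest parental peaks near a gene end were MRPS31 (mitochondrial ribosome), BRF2 (an RNA polymerase III factor), AURKAIP1 (mitochondrial ribosome), SF3A3 (splicing) and LZIC. Their parental folds ran from 21.1 at LZIC to 23.6 at MRPS31, and their peaks had folds of 16.8, 21.4, 15.9, 14.4 and 21.2 in the knockout list, in that order. The summits lay 11 bp from the end of MRPS31 (chromosome 13, 40729128 to 40771190), 72 bp from that of BRF2 (chromosome 8, 37843268 to 37849861) and 179 bp from that of AURKAIP1 (chromosome 1, 1373736 to 1375207). They lay 53 bp from the end of SF3A3 (chromosome 1, 37956975 to 37990022) and 3 bp from that of LZIC (chromosome 1, 9922118 to 9943391), where NMNAT1 shared the peak.

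Whether a control peak was kept followed its strength. In 4 equal bins of parental fold, from weakest to strongest, the share of control-shared peaks with a knockout peak was 5.92% (4.34 to 7.87), 35.2% (31.7 to 38.7), 80.9% (77.8 to 83.6) and 97.4% (96.0 to 98.5). The weakest bin spanned folds of 2.05 to 4.29 and the strongest 9.61 to 23.6. The control pair had a gradient of its own. In 10 equal bins of ROSA26 fold, the share with a parental peak was 10.9% in the weakest bin, 54.8% in the third, 94.8% in the fifth and 100% from the seventh on. In the strongest of the 4 bins of parental fold, 19 of 742 control-shared peaks had no knockout peak.

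**Figure D2:**
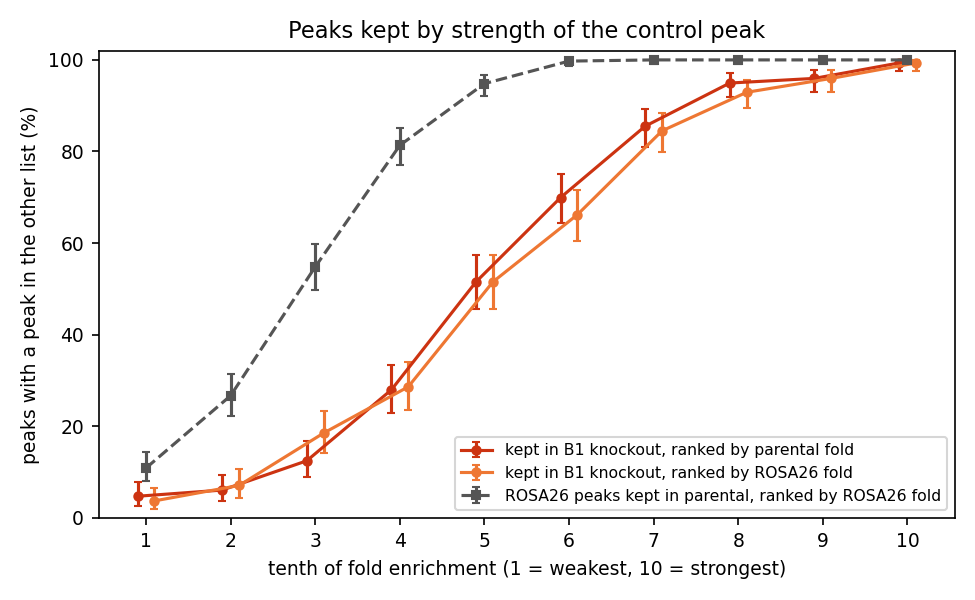
Share of peaks with a peak in another list (y axis, %) by bin of fold enrichment within the list used for ranking (x axis, 10 equal bins), with exact 95% intervals as bars and 1 library per condition. Control-shared peaks pass from 4.71% to 99.3% with a knockout peak along parental fold, and ROSA26 peaks from 10.9% to 100% with a parental peak along ROSA26 fold.

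The 5 strongest control-shared peaks without a knockout peak had parental folds of 12.1 to 12.9. The strongest, on chromosome 19 from 53961614 to 53962396, lay 878 bp outside an end of CACNG8, a calcium channel subunit gene, with folds of 12.9 in the parental and 16.0 in the ROSA26 list. The next was on chromosome 19 from 44207086 to 44207792, 135 bp outside an end of ZNF227, a zinc finger gene (12.8 and 11.7). The third was on chromosome 2 from 112584114 to 112584809, 35 bp inside an end of CHCHD5, a mitochondrial protein gene (12.1 and 16.2). One peak, on chromosome 11 from 39161549 to 39162234, was inside no protein-coding gene and within 1 kb of no gene end (12.1 and 12.98). The last was on chromosome 15 from 90929841 to 90930481, near the ends of UNC45A and HDDC3 (12.1 and 11.6). Scaled down to the background of the knockout library, these 5 parental peaks kept a −log10 p of 86.5 to 124, above the median knockout value of 34.2.

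Peaks found in the knockout alone were few and weak. All 24 had a fold below the median of the knockout list (5.81), and 18 lay on chromosomes 1 to 22 and X, which the gene positions cover. Of these 18, 2 had a summit within 1 kb of a gene end (11.1%, 1.37 to 34.7). The 5 strongest were on chromosome Y from 56886827 to 56887170 (fold 4.39), on chromosome 20 from 2102053 to 2102393, 307 bp inside an end of STK35 (3.91), and on chromosome 2 from 21535850 to 21536191 (3.48). The others were on chromosome 16 from 25807008 to 25807341 inside HS3ST4 (3.30) and on chromosome 13 from 104604267 to 104604622 (3.196). Whether the line carries a chromosome Y was not checked here, so the peak listed there is not shown to be a site of these cells.

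GABPA peaks lay mostly at gene ends in all 3 libraries. A summit within 1 kb of an end of a protein-coding gene was found for 80.4% of parental (79.0 to 81.8), 76.2% of ROSA26 (74.8 to 77.6) and 86.1% of knockout peaks (84.3 to 87.7), against 2.35% (2.14 to 2.56) of random positions. Of the summits near a gene end, 83.1%, 81.3% and 87.3% lay within 200 bp. Control-shared peaks with a knockout peak were near a gene end in 87.3% (85.6 to 88.9) and those without in 74.0% (71.5 to 76.3). Above the median parental fold of control-shared peaks the shares were 88.2% (86.3 to 89.9) and 87.0% (80.8 to 91.7), and below it 83.6% (79.0 to 87.6) and 72.2% (69.6 to 74.7). Of ROSA26 peaks without a parental peak, 59.4% (56.1 to 62.6) were near a gene end. With equal list lengths the shares near a gene end were 87.9%, 87.5% and 86.1% for parental, ROSA26 and knockout, so the order of the whole lists was not kept.

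Genes whose ends lie close to those of a neighbour carried GABPA often. Another gene's end lay within 1 kb for 28.6% of all protein-coding genes (28.0 to 29.2), and for 52.6% (50.8 to 54.4), 51.2% (49.5 to 52.8) and 55.7% (53.4 to 58.0) of the genes with a parental, ROSA26 and knockout peak. Part of this excess arises because 1 peak between neighbouring genes counts for both. Control-shared peaks near the ends of 2 or more genes had a knockout peak in 65.1% (61.3 to 68.7), those near 1 gene in 56.6% (54.2 to 58.9) and those near none in 37.1% (33.1 to 41.3). Random sets of peaks matched on strength had median shares of 62.7, 56.9 and 38.9%, so most of this spread went with peak strength. Among those sets the observed shares stood at percentiles 98.3, 25.3 and 6.69.

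In all, 3090 genes had a parental, 3692 a ROSA26 and 1860 a knockout peak near an end. Both controls marked 3062 genes, of which 1850 (60.4%, 58.7 to 62.2) also had a knockout peak and 1212 did not. Of the 27 gene lists, 18 lay above the 97.5th percentile of matched random lists in the parental library. The random lists were matched on neither CpG content nor expression, so a part played by either in this excess was not tested. The 9 others were ATP synthase (percentile 92.8), DNA replication (97.2), autophagy (96.9), cell cycle (34.8), and the MAPK, ETS, melanocyte, other skin and silent gene lists. Genes of tissue-restricted programmes were rarely marked, but not outside the central 95% of random lists. The silent, melanocyte and other skin lists stood at percentiles 2.67, 2.84 and 10.9 in the parental library, where random medians were 14.3, 9.52 and 11.1%, and the silent list at 1.54 in ROSA26, on the edge by ties. None of 21 genes silent outside other organs had a peak in any library. Of 21 genes of the melanocyte lineage, the origin of this cell line, 1 had a peak, in ROSA26 alone (RAB27A, fold 3.95, named after its value was seen). Of 27 marker genes of other skin cell types, 1 was marked in all 3 libraries, KRT10, whose summit lay 951 bp inside the gene (folds 16.0, 22.6 and 6.90).

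Genes of RNA splicing and protein synthesis were among those most often marked by GABPA. Of 42 spliceosome genes, 30 had a parental, 31 a ROSA26 and 22 a knockout peak, with SF3A3 and U2AF2 kept and SF3B1 (parental fold 6.53) and SF3B3 (5.78) not kept. Of 79 cytosolic ribosomal protein genes, 52, 56 and 34 were marked. RPS7 (parental fold 20.1) and RPS18 (19.3) were kept, and RPS19 (9.59) and RPL19 (6.48) had no knockout peak. Of 36 translation initiation factors, 19, 21 and 14 were marked, with EIF2B1 (16.6) and EIF4E2 (15.2) kept and EIF3D (6.77) and EIF1 (5.33) not kept. Of 37 aminoacyl-tRNA synthetases, which load amino acids onto tRNA, 20, 24 and 13 were marked, with CARS1 and HARS1 kept and QARS1 and NARS1 not kept. Of 56 genes of tRNA and rRNA modification and ribosome biogenesis, 30, 34 and 24 were marked, with NOC3L and DDX21 kept and TRMT10B and TRMT2A not kept. Each of these 5 lists lay above the 97.5th percentile in the 3 libraries. The shares kept, 22 of 30, 34 of 52, 14 of 19, 13 of 20 and 24 of 30, lay at percentiles 77.5, 78.0, 40.0, 88.6 and 89.8 of lists of equal peak strength.

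Mitochondrial genes were marked in each functional class. Of 77 mitochondrial ribosomal protein genes, 35 had a parental, 39 a ROSA26 and 27 a knockout peak, with MRPS31 and MRPL21 kept and MRPS33 (8.16) and MRPL2 (7.74) not kept. Of 27 factors of mitochondrial DNA expression, 17, 20 and 16 were marked, with SSBP1 (16.9) and TUFM (16.5) kept. PRORP (3.75), a component of mitochondrial RNase P, was the 1 gene of the 17 in both controls without a knockout peak. Of 28 genes of mitochondrial protein import, 17, 18 and 14 were marked, with TIMM29 (19.3) and PMPCB (14.4) kept and TIMM10 (5.10) and TOMM40 (4.55) not kept. Of the ribosomal protein genes 27 of 35 were kept (percentile 66.9) and of the expression factors 16 of 17 (89.5). Of the import genes 14 of 17 were kept, at percentile 97.9 among lists of equal strength, and 4 of 5 alternatives put the list below the 97.5th percentile (lowest 94.98).

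Respiratory chain genes were marked in each complex. Of 23 cytochrome c oxidase and assembly genes, 13 had a parental, 13 a ROSA26 and 9 a knockout peak, with SCO1 and SURF1 kept and COX7C (7.03) and COX17 (5.00) not kept. Of 36 complex I genes 14, 15 and 9 were marked, with NDUFS3 (18.5) and NDUFB3 (12.8) kept and NDUFA2 and NDUFA12 not kept. Of 13 genes of complexes II and III 6, 6 and 4 were marked, with SDHD and UQCRH kept and SDHB and UQCR11 not kept. Of 18 ATP synthase genes 6, 8 and 6 were marked, and all 6 in both controls were kept, ATP5MK (18.4) and ATP5PF (13.2) among them. Of 12 genes known as GABP targets from earlier work 7, 8 and 4 were marked. TFB2M (11.3) and UHMK1 (9.03) were kept, and RB1 (6.46), the retinoblastoma gene, and COX4I1 (4.45) were not. These 5 shares kept lay between percentiles 31.7 and 92.7 of lists of equal strength.

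**Figure D3:**
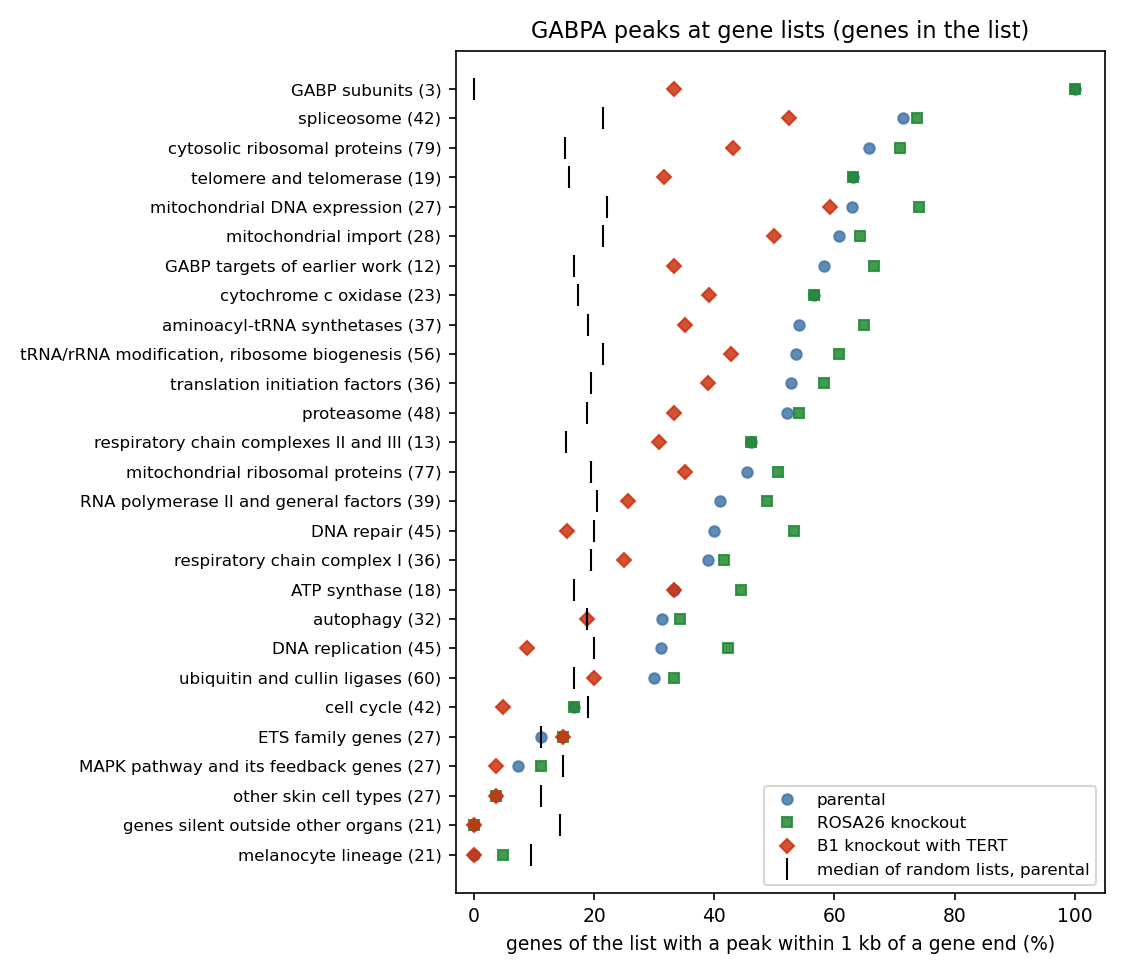
Share of the genes of each fixed list (number of genes in brackets) with a GABPA summit within 1 kb of a gene end (x axis, %), 1 library per condition, with a black tick at the median of matched random lists for the parental library. Spliceosome genes reach 71.4% in the parental library, and no gene of the tissue-restricted comparison list has a peak.

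Few of the DNA replication genes marked in both controls had a knockout peak. Of 45 genes, 14 had a parental, 19 a ROSA26 and 4 a knockout peak. Of the 14 marked in both controls, 4 were kept (28.6%, 8.39 to 58.1) against a median of 50% in lists of equal strength, at percentile 1.46, with ties placing the value on the edge of the central 95%. The flap endonuclease gene FEN1 (parental fold 12.2) and the origin recognition gene ORC3 (11.7) were kept, and ORC4 (6.65) and MCM10 (6.35) had no knockout peak. The list rose above the 2.5th percentile when summits had to lie within 500 bp (3.65) or counted for the nearest gene only (6.08, 1 of 8 genes kept). It stayed below when matched on ROSA26 fold (0.15), within 2 kb (1.78) or with summits anywhere in the gene (2.24). Of 42 cell cycle genes 7, 7 and 2 were marked, E2F4 (14.6) and CKS1B (10.1) kept and RB1 and CKS2 among those not kept. Of 45 DNA repair genes 18, 24 and 7 were marked, FANCM (13.95) and ERCC3 (13.1) kept and ERCC5 (8.01) and XRCC5 (7.68) not kept. Their shares kept, 2 of 7 and 7 of 18, lay at percentiles 9.80 and 14.2.

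**Figure D4:**
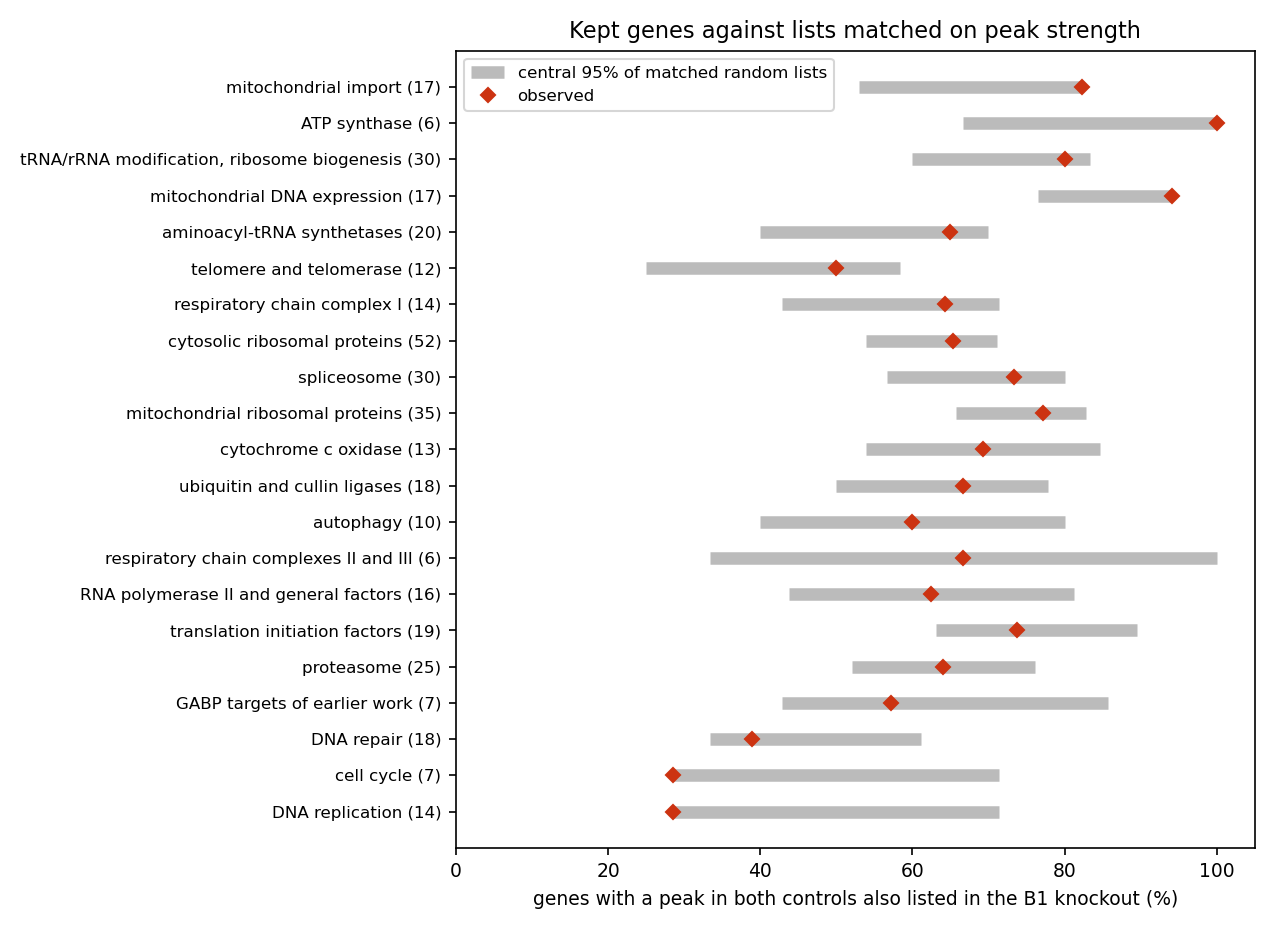
Share of genes with a peak in both controls that also had a B1 knockout peak (x axis, %), for each list with at least 5 such genes (number in brackets), with grey bars for the central 95% of random lists matched on parental fold and 1 library per condition. No list lies outside its range. ATP synthase, mitochondrial DNA expression and mitochondrial import (82.4%) sit on the upper edge, and DNA replication (28.6%) and cell cycle on the lower edge. ATP synthase, with all of its 6 genes kept, could not lie above its range, which reaches 100%.

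Protein turnover, transcription and telomere genes were marked as well. Of 48 proteasome genes 25, 26 and 16 had a parental, ROSA26 and knockout peak, PSMG3 (15.01) and PSMC2 (14.4) kept and PSMD12 (7.97) and PSMD13 (6.25) not kept. Of 60 ubiquitin and cullin ligase genes 18, 20 and 12 were marked, COPS2 (14.6) and UBE2G2 (12.7) kept and CUL7 (7.74) and CUL2 (5.44) not kept. Of 32 autophagy genes 10, 11 and 6 were marked, GABARAP and ATG2B kept and RB1CC1 and ATG5 not kept. Of 39 genes of RNA polymerase II and general factors 16, 19 and 10 were marked, GTF2H3 and TAF13 kept and TAF1 (9.004) and POLR2G (6.02) not kept. Of 19 telomere and telomerase genes 12, 12 and 6 were marked. SHQ1 (12.5), an assembly factor of telomerase RNA particles, and the helicase gene RTEL1 (11.1) were kept, and the shelterin gene TINF2 (5.32) and STN1 (3.62) were not. Their shares kept lay between percentiles 37.5 and 80.9 of lists of equal strength. Of the 3 GABP subunit genes 1 was kept (percentile 3.32, and too few genes for a statement on the list).

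The MAPK and ETS family lists lay inside the central 95% of random lists in all 3 libraries. Of 27 MAPK pathway and feedback genes 2 had a parental, 3 a ROSA26 and 1 a knockout peak, at percentiles 9.20, 12.3 and 13.4. Of 27 ETS family genes 3, 4 and 4 were marked, at percentiles 39.9, 45.8 and 90.6. All 3 in both controls were kept, GABPA and ETV3 (7.16) among them, at percentile 98.0 for the share kept, which ranged from 61.5 to 99.7 over alternatives with so few genes.

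The share of peaks kept varied by chromosome. Among sets of control-shared peaks matched on strength, chromosomes 7 (66 of 140 kept, 47.1%, 38.7 to 55.8) and 13 (21 of 52, 40.4%, 27.0 to 54.9) lay below the central 95%. Chromosomes 9 (81 of 136, 59.6%, 50.8 to 67.9), 11 (110 of 168, 65.5%, 57.8 to 72.6) and 20 (67 of 108, 62.0%, 52.2 to 71.2) lay above it, and chromosome 1 (162 of 290, 55.9%, 49.9 to 61.7) lay on its upper edge. For ROSA26 peaks looked up in the parental list, 6 of 23 chromosomes lay outside the central 95% and 1 on its edge. Chance gives about 1.15 of 23 in either comparison.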

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

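No paired analysis was possible because each condition had 1 library, and for the same reason no library could be left out. The alternatives were chosen before the data were examined, except the thresholds at the 10th percentile, the 25th percentile and the median, the count of summits anywhere in the gene and the assignment to the nearest gene, which were chosen after seeing the data. Every alternative that needs the genome sequence (ETS motifs) was not run. The share of control-shared peaks with a knockout peak moved outside its interval in 5 alternatives, to 88.16% with equal list lengths, 58.18% with −log10 q of at least 10 in the controls only, and after scaling 65.3% at the 10th percentile, 73.93% at the 25th percentile and 88.37% at the median of knockout −log10 p as threshold. The share of parental peaks with a ROSA26 peak was 97.55% with reciprocal overlap of 50%, 96.33% with summits within 100 bp and 94.1% with equal list lengths. The share of knockout peaks with a peak in both controls was 99.08% and 99.46% with −log10 q of at least 5 and 10, 90.54% with reciprocal overlap, 95.12% with close summits and 82.95% with equal list lengths. The share of parental peaks near a gene end was 82.08% with −log10 q of at least 10, 87.89% with equal list lengths, 77.08% within 500 bp and 83.2% within 2 kb. For ROSA26 it was 77.77% and 79.72% with −log10 q of at least 5 and 10, 87.47% with equal lengths, 72.23% within 500 bp and 79.34% within 2 kb. For the knockout it was 83.73% within 500 bp and 87.77% within 2 kb. The number of gene lists below the 2.5th or above the 97.5th percentile for the share kept, with ties counted as 0.5, was 1 within 500 bp, 1 within 2 kb, 1 with summits anywhere in the gene and 0 with the nearest gene only, where 19 lists had at least 5 genes, against 2 of 21 in the reported setting, both on the edge of the central 95% and not beyond it; the cause was not tested. The other 29 values stayed within their interval or within 1.5 times the reported count. Over the percentiles of single lists, 106 kept their side of the 2.5th and 97.5th percentiles, 8 moved between them and 1 moved past them. The lists hold no read totals, and what depth limits among the weakest peaks was not tested apart: a missing peak there is not shown to be a lost site.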

Other observations

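The tests on the cell cycle and DNA repair lists and both tests of depth at higher −log10 p thresholds were chosen only after the results they bear on had been seen. Genes named here that fall outside the naming rule were also chosen after their values were seen.

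Among DNA replication genes, those without a knockout peak included subunits of the replicative helicase and its loader. MCM4 had folds of 5.40 in the parental and 5.93 in the ROSA26 list, MCM3 3.57 and 6.24, CDC45 5.14 and 5.94, GINS2 3.79 and 5.21, and ORC2 3.81 and 4.99. RFC4, a clamp loader subunit, had 5.26 and 6.04, POLA1, the catalytic subunit of DNA polymerase alpha, 5.80 and 7.95, and RPA2, a single-strand binding protein, 4.90 and 6.94. MCM7 (7.11 and 11.4, with 5.55 in the knockout) and RFC2 (11.2 and 13.99, with 9.79) were marked in all 3 lists. The peak at MCM4 is shared with PRKDC, a DNA repair gene. BRCA1 had a ROSA26 peak only (fold 2.70), and ELK4, an ETS family gene, had one in ROSA26 (3.84) and in the knockout (3.66).

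Fewer peaks were listed in the B1 knockout library, whose background pileup in own reads was 64.0% of the parental one. The scaling below used the backgrounds after the scale factor, 13.3 (parental), 14.2 (ROSA26) and 9.11 (knockout). A depth test set in advance used the lowest knockout −log10 p, which 2965 of 2969 control-shared peaks pass after scaling, so it could hardly fail and was replaced, with the values at higher thresholds already known. Against lower depth as the sole explanation, 65.3% (63.39 to 67.18) of the control-shared peaks that reach the 10th percentile of knockout −log10 p after scaling had a knockout peak, and 87.7% (86.6 to 88.8) of ROSA26 peaks that reach the same −log10 p at the parental background had a parental peak. At the 25th percentile the share was 73.9%, against 94.1% at the same −log10 p in the control pair. At the median it was 88.4% (86.7 to 89.9), against 99.3% (98.9 to 99.6) in the control pair. The gap in percentage points was smallest at the median, where both shares were nearest their upper limit. The smaller gap there thus does not show a smaller excess of missing peaks in the knockout library. For a fall in enrichment by a strictly equal factor at every site, peaks above the ROSA26 fold at which 50% were kept were examined. At 1.5 to 2.5 times that fold, 4.08% of control-shared peaks (2.77 to 5.77, 30 of 736) were not kept. In the control pair it was 0.92% of ROSA26 peaks (0.42 to 1.75, 9 of 975). The 50% point lay at a fold of 7.0 for the knockout and 3.61 for the control pair. The ranges of fold and the peak sets are thus unlike, and the knockout library is shallower. The prediction set in advance counted a higher share not kept against an equal factor. Because of these differences the control pair does not show what an equal factor would give, so the comparison does not decide it. A fall in enrichment, equal or unequal over sites, from the chromatin preparation, the clone or the knockout of exon 2 of the B1 subunit, stays open. No replicate separates these.

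The 161 control-shared peaks above the median parental fold without a knockout peak include those near ZDHHC4, ZNF233 and ASXL1 besides those named in the report. The depth test set in advance for them had the same fault and was replaced in the same way. Against lower depth as their sole explanation, 9.78% (8.29 to 11.4, 141 of 1442) of the peaks of this upper part that reach the median knockout −log10 p after scaling had no knockout peak, and 0.68% (0.39 to 1.11, 16 of 2339) of ROSA26 peaks that reach the same value at the parental background had no parental peak. These 1442 peaks are part of those compared at the median above, with the same control pair, so the result is not separate evidence. Copy number differences between the lines would place such peaks side by side, and 11.63% (6.66 to 18.5) of the 129 with such a strong neighbour within 1 Mb had a neighbour that was also not kept, inside the 4.13 to 18.4% of sets reshuffled within strength. The prediction set in advance counted a share inside that range against copy number. The interval, which rests on 15 such peaks, reaches the upper end of that range. Peaks that are each other's nearest neighbour also count in both directions, so copy number stays open.

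A hypothesis from these lists is that GABPA at DNA replication genes may depend more on the B1 subunit than at other genes of equal peak strength. The B1 knockout, the TERT knock-in and the clone share 1 library, so nothing here ties a difference to the B1 subunit in particular. None of the 21 lists with at least 5 genes lay outside the central 95% of its random lists: 5 lay on an edge, and 2 of these, DNA replication among them, passed the 2.5th or 97.5th percentile only with ties counted as 0.5. In the control pair the DNA replication list lay at percentile 7.52. A first test joined the cell cycle, DNA repair and DNA replication lists (percentile 0.38), but it held the list that gave rise to the hypothesis and decides nothing. Without the DNA replication genes, the cell cycle and DNA repair lists had 9 of 24 genes kept, at percentile 6.9, against 63.2 in the control pair. This lies neither below the 2.5th nor above the 50th percentile, so chance remains open.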
